A study of Mus musculus with 24 samples.

How the data were processed

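Total RNA of kidneys from male and female mice, collected in the middle of the active or of the inactive period, was sequenced on an Illumina instrument after poly A selection. The labels give 100 ng of RNA per library, a Zymo Direct-Zol extraction and deidentified samples. There were 24 libraries, 6 each of active females, inactive females, active males and inactive males, grouped from the labels. The titles number the libraries, and each number is shared by a male and a female of the same period. The labels do not say that this pairs them, so they were not paired.

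The signal in the deposited table is, per the labels and the values, gene counts that the authors divided by a size factor per library. The notes of the submitters name Trim Galore 0.6.10, Subread 2.0.6, featureCounts, DESeq2 1.28.1 and the build GRCm39. The annotation release, the aligner settings, the strand setting and the role and order of these steps are not given in the sources used here. The table holds 56748 gene identifiers, of which 52073 have a symbol in the reference annotation and carry 99.2% of the signal. Of all identifiers 21416 are at 0 in every library, and 68 symbols are shared by several identifiers, in which case the most abundant kept the symbol. The reference annotation held here is of the older build GRCm38, so it was used for symbols, gene lengths and GC content and not for coordinates. Arntl and G6pc are older symbols of Bmal1 and G6pc1.

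Because each library has 1 factor, whole reads could be recovered by dividing by the step between its values. All values above 0 were whole within 0.05 in every library. Recovered reads numbered 31.0 to 39.3 M per library, with means of 34.3 ± 2.60 M in active females, 34.4 ± 2.80 in inactive females, 34.3 ± 1.66 in active males and 34.8 ± 1.92 in inactive males. The size factors ranged from 0.828 to 1.28. Counting error is largest for genes near the filter of 10 normalized counts, and it is part of every SD given.

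Genes with a mean normalized count of at least 10 over all libraries were tested, 17333 in number, 3115 of them predicted genes known by model identifiers. Values were taken as log2 of the normalized count plus 1. All 24 libraries were fitted together with limma 3.58.1 in R 4.3.3, with a trended and robust variance prior and 20 residual degrees of freedom. There were 5 contrasts, active against inactive in each sex, the difference between these (the period by sex interaction), and male against female in each period. P-values were adjusted per contrast by Benjamini and Hochberg, and genes with an adjusted p under 0.05 were called. Levels are means ± SD, and log2 folds are given ± SE.

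Lists of genes for the clock, stress responses, metabolism, transport, sex-biased expression and cell types, 46 in all, were written before the data were examined. Of these 45 had enough members, which made 225 tests with camera in limma, at a preset correlation of 0.01 between genes, adjusted together. Each list was tested again with a correlation estimated from its members. Calls within a list were counted with the adjustment over all genes and with an adjustment over the list alone. The overlap of calls between comparisons was tested with the exact test of Fisher.

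Genes to name were fixed by a rule. For each contrast these were the 6 largest increases and the 6 largest decreases among called genes with a mean of at least 50 in the higher group and no overlap of the groups, leaving out model identifiers. To these came up to 4 members of each list with the smallest p, and all clock genes. A few genes that this rule picks are not reported here. For genes with at most 3 reads in a group, ratios are lower bounds against 3 reads over the 6 libraries where there were no reads, and otherwise come with a 95% counting interval.

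Alternatives were pseudocounts of 0.5 and 5, no filter on low values, rescaling by TMM factors, by the upper quartile or to equal totals, only the 2 groups compared, library weights, a plain variance prior, edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, each library left out in turn, and the number in the titles as a block. The method was tested on simulated data made from these libraries, with 200 of 17333 genes changed. Of genes changed 1.5-fold, 65.7% were recovered for the period in females, 62.7% in males, 50.7% for the interaction and 47.8% for sex in the active period. Of genes changed 4-fold, 98.5%, 92.4%, 86.4% and 97.0% were, with 6, 8, 9 and 3 false calls. The simulated groups differed in these 200 genes alone, and their size factors were known. In the data 15.0% of genes were called for the period in females and 60.6% for sex in the active period. The simulated shares and false calls therefore need not hold there. Random splits of the libraries, matched lists and permutations were run as given in the closing notes. Reads were not analysed here, and neither were splice forms, proteins or kidney function.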

Results

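Kidneys of mice collected in the middle of the active period differed from kidneys collected in the middle of the inactive period in genes of the circadian clock and in single genes of protein folding and transport. Males and females differed far more than the periods did. The question was how kidney RNA differs between the periods in each sex, and whether that difference is the same in males and females. Poly A RNA was profiled in 24 libraries, 6 each of active females, inactive females, active males and inactive males. All values are the authors' normalized counts, given as mean ± SD, n = 6 libraries per group.

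The first principal component held 49.6% of the variance and parted the sexes, and the next held 7.39% and parted the periods. The Y-linked Ddx3y, an RNA helicase, was at 1379 to 2361 in every male library and at most 4.96 in every female one. Xist, the RNA that silences the inactive X chromosome, was at 25440.0 to 30894 in females and 2.18 to 18.4 in males. The recorded sex therefore holds for all 24 libraries. The sources used here do not say whether each library is a separate animal. The p-values measure the spread between these samples, which may be partly technical. The gene lists, the rule for naming genes and the alternatives were set before the data were examined, except where the closing notes say otherwise.

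In females the molecular clock was in opposite states in the active and inactive periods. Genes that the clock drives towards the active period were high, and the Rev-erb and PAR bZIP genes were low. Many genes that help proteins fold in the endoplasmic reticulum and the cytosol were higher in the active period, as were several targets of glucocorticoid hormones, though these lists did not pass with an estimated correlation (adjusted p = 0.119, 0.455 and 0.605). Single sugar, amino acid and sodium uptake genes of the proximal tubule were lower, while further along the nephron the sodium channel gene Scnn1a and the potassium channel gene Kcnj1 were higher and the potassium channel gene Kcnma1 was lower. Genes of cell division and of the respiratory chain did not move as groups.

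Among genes with separated groups and a mean of at least 50, the largest rise in females was in Arntl (ENSMUSG00000055116), the clock activator also called Bmal1, at 1174 ± 148 and 108 ± 55.6 normalized counts, log2 fold 3.62 ± 0.34, adjusted p = 1.82e-07. Its lowest active library, at 924, lay above its highest inactive library, at 164. Its relative Npas2 (ENSMUSG00000026077) rose from 47.0 ± 12.7 to 430.2 ± 105 (log2 fold 3.17 ± 0.21, adjusted p = 1.26e-11). The repressor Cry1 (log2 fold 2.85 ± 0.26, adjusted p = 1.24e-07), the repressor Nfil3 (log2 fold 2.28 ± 0.21, adjusted p = 5.91e-08) and Clock, the partner of Bmal1 (log2 fold 0.55 ± 0.06, adjusted p = 7.17e-08), were higher too. All 6 genes of the Bmal1 arm passed (camera adjusted p = 8.87e-19, and adjusted p = 1.40e-06 with an estimated correlation).

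The other arm of the clock moved the other way. Dbp (ENSMUSG00000059824), a PAR bZIP transcription factor, was 30.1-fold lower in the active period, at 70.4 ± 15.2 and 2147 ± 429 normalized counts, log2 fold -4.91 ± 0.22, adjusted p = 5.15e-13. Nr1d1 (ENSMUSG00000020889), the Rev-erb alpha repressor, was lower (log2 fold -4.58 ± 0.17, adjusted p = 3.14e-15). The repressor Ciart (log2 fold -2.64 ± 0.25, adjusted p = 2.96e-08), the Rev-erb beta gene Nr1d2 (log2 fold -2.47 ± 0.11, adjusted p = 1.09e-13), the period gene Per3 (log2 fold -1.70 ± 0.13, adjusted p = 5.39e-09), the repressor Bhlhe41 (log2 fold -1.33 ± 0.17, adjusted p = 1.79e-06) and the PAR bZIP gene Tef (log2 fold -1.08 ± 0.09, adjusted p = 1.34e-08) were lower. Of the 13 genes of this arm, 8 were lower and 5 did not pass (8 lower and 1 higher adjusted over the list alone, camera adjusted p = 1.52e-12, and adjusted p = 0.0275 with an estimated correlation). The eighth, Hlf, a PAR bZIP gene (log2 fold -0.17 ± 0.06, adjusted p = 0.0378), loses its call without female active replicate 3, 4, 5 or 6 or female inactive replicate 3, 5 or 6. Per2 (log2 fold 0.57 ± 0.22, adjusted p = 0.0833) and Per1 (log2 fold 0.01 ± 0.38, adjusted p = 0.995), which encode period proteins, did not pass in females.

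**Figure D1:**
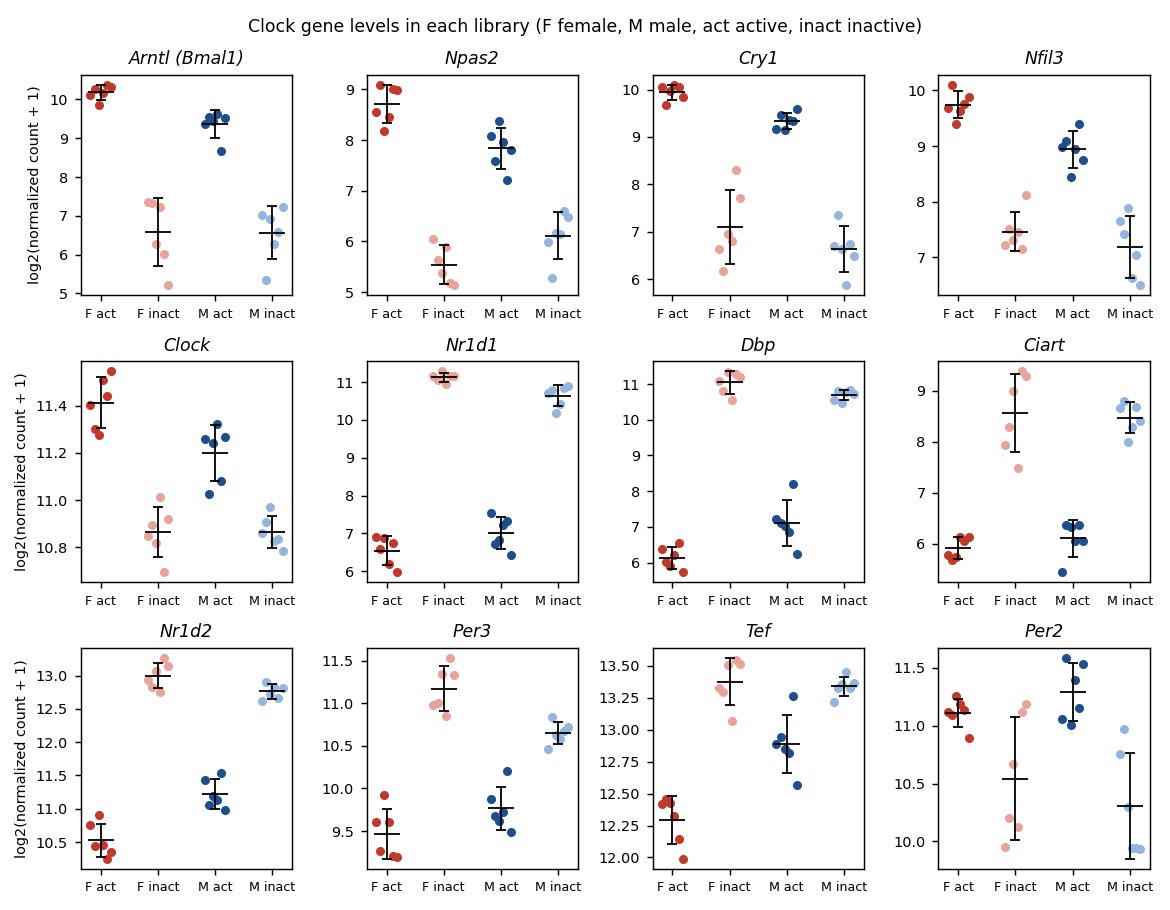
Levels of 12 clock genes in kidney libraries of active and inactive females and males. Points are libraries, 6 per group, and black marks are mean ± SD of log2(normalized count + 1). Arntl (Bmal1), Npas2, Cry1, Nfil3 and Clock were higher in the active period in both sexes, and Nr1d1, Dbp, Ciart, Nr1d2, Per3 and Tef lower. Per2 passed in males alone, and its difference between the sexes did not pass (adjusted p = 0.496).

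Protein folding was the next pattern in females. Of 22 genes of the unfolded protein response, 16 were higher and 6 did not pass (17 higher adjusted over the list alone, camera adjusted p = 8.87e-19, and adjusted p = 0.119 with an estimated correlation). The endoplasmic reticulum chaperone Hyou1 rose 2.38-fold, from 2379 ± 508 to 5591 ± 586 (log2 fold 1.25 ± 0.12, adjusted p = 8.05e-08). The chaperone Hsp90b1 (log2 fold 0.95 ± 0.11, adjusted p = 2.73e-06) and the co-chaperone Dnajb11 (log2 fold 0.78 ± 0.10, adjusted p = 2.39e-06), both of the same compartment, rose too. Of 16 heat shock genes 9 were higher and 7 did not pass (10 higher over the list alone, camera adjusted p = 6.53e-08, and adjusted p = 0.455 with an estimated correlation). Among these were the cytosolic chaperone Hsp90aa1 (log2 fold 0.96 ± 0.15, adjusted p = 1.57e-04) and the co-chaperones Stip1 (log2 fold 0.74 ± 0.12, adjusted p = 1.04e-04) and Ahsa1 (log2 fold 0.66 ± 0.11, adjusted p = 2.58e-04). Cirbp, which encodes an RNA-binding protein induced by mild cold, fell (log2 fold -0.57 ± 0.12, adjusted p = 0.00145), and the related Rbm3 did not pass (adjusted p = 0.790).

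Of 15 glucocorticoid targets 6 were higher, 1 lower and 8 did not pass in females (7 higher and 1 lower over the list alone, camera adjusted p = 0.0117, and adjusted p = 0.605 with an estimated correlation). Tsc22d3, the glucocorticoid-induced leucine zipper gene, rose 2.18-fold (log2 fold 1.13 ± 0.22, adjusted p = 0.00103). The co-chaperone of the glucocorticoid receptor Fkbp5 (log2 fold 0.74 ± 0.17, adjusted p = 0.00478) and the cell cycle inhibitor Cdkn1a (log2 fold 0.96 ± 0.17, adjusted p = 1.87e-04) rose as well. Sgk1, the kinase that raises sodium channel activity, was at 15255 ± 2662 and 6414 ± 1626 normalized counts, log2 fold 1.27 ± 0.29, adjusted p = 0.00474. Of 16 genes of WNK, SGK and aldosterone signalling, 5 were higher and 11 did not pass (6 higher over the list alone, camera adjusted p = 0.0101, and adjusted p = 0.207 with an estimated correlation).

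Transport genes of females moved both ways along the nephron. The sodium channel subunit Scnn1a (log2 fold 0.56 ± 0.06, adjusted p = 1.82e-07), the potassium channel of the thick ascending limb and collecting duct Kcnj1 (log2 fold 0.31 ± 0.05, adjusted p = 1.35e-04) and the vasopressin receptor Avpr1a (log2 fold 1.11 ± 0.11, adjusted p = 2.03e-08) rose. The proximal sodium-proton exchanger Slc9a3 (log2 fold -0.45 ± 0.07, adjusted p = 2.29e-05), the neutral amino acid transporter Slc6a19 (log2 fold -1.21 ± 0.11, adjusted p = 4.93e-08), the glucose transporter Slc2a2 (log2 fold -0.59 ± 0.06, adjusted p = 4.74e-08) and the carnitine and ergothioneine transporter family member Slc22a4 (log2 fold -0.71 ± 0.09, adjusted p = 5.35e-06) fell. So did the large-conductance potassium channel Kcnma1 (log2 fold -1.09 ± 0.22, adjusted p = 5.94e-04) and the water and glycerol channel Aqp3 (log2 fold -0.49 ± 0.07, adjusted p = 5.31e-06). Of 26 sodium, potassium and chloride transport genes, 4 were higher and 4 lower (camera adjusted p = 0.756). Of 28 organic ion transporters 1 was higher and 6 lower, also adjusted over the list alone (camera adjusted p = 0.0472, and adjusted p = 0.655 with an estimated correlation). Of 10 markers of the first proximal tubule segments 4 were lower and 6 did not pass (7 lower over the list alone, camera adjusted p = 2.47e-05, and adjusted p = 0.208 with an estimated correlation).

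Single metabolic genes also changed in females. G6pc, the glucose-releasing phosphatase of gluconeogenesis, rose 2.36-fold (log2 fold 1.24 ± 0.17, adjusted p = 3.86e-05), while Cpt1a, which brings fatty acids into mitochondria (log2 fold -0.39 ± 0.06, adjusted p = 4.99e-05), and Ppara, the receptor that drives fatty acid oxidation (log2 fold -0.54 ± 0.11, adjusted p = 8.03e-04), fell. Neither gluconeogenesis (1 higher and 1 lower of 7, camera adjusted p = 0.283) nor fatty acid oxidation (2 higher and 4 lower of 27, camera adjusted p = 0.915) passed as a list. The autophagy genes Wipi1 (log2 fold -0.60 ± 0.09, adjusted p = 3.44e-05) and Gabarapl1 (log2 fold -0.38 ± 0.05, adjusted p = 6.77e-06) fell, with 6 of 17 autophagy genes lower (camera adjusted p = 0.108). Of 25 cholesterol synthesis genes 6 were higher and 1 lower (9 higher and 2 lower over the list alone, camera adjusted p = 0.0117, and adjusted p = 0.616 with an estimated correlation), and 10 were higher without female active replicate 1. Cyp26b1, which breaks down retinoic acid, had a wide spread, at 1259 ± 1059.5 and 198 ± 122 normalized counts, log2 fold 2.51 ± 0.65, adjusted p = 0.0115. By the same measure the largest falls outside the clock were in Nrap, which encodes an actin-anchoring protein (log2 fold -1.89 ± 0.24, adjusted p = 1.74e-06), and Lrrc55, a subunit partner of large-conductance potassium channels (log2 fold -1.86 ± 0.40, adjusted p = 0.00141).

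Across all 17333 tested genes 1382 were higher and 1210 lower in active females at an adjusted p under 0.05, and 198 of these changed at least 2-fold. The balance depends on the scaling, with 1199 higher and 1415 lower by the upper quartile and 1019 and 1570 by equal totals. The median fold of the called genes was 1.26. In each called gene named here other than Hlf, Cirbp and Fkbp5, all 6 active libraries lay on the same side of all 6 inactive ones. The 58 nuclear respiratory chain genes (camera adjusted p = 0.785) and the 24 cell cycle genes (camera adjusted p = 0.257) did not pass as lists, and of 82 ribosomal protein genes 1 was lower.

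In males the clock genes called in females stood in opposite states in the same directions, apart from Hlf, which did not pass. Many protein-folding genes were higher in the active period here too, though these lists did not pass with an estimated correlation (adjusted p = 0.605 and 0.536). The glucocorticoid-induced genes Tsc22d3 and Fkbp5 were also higher. Males had a strong fall of the RNA of Cyp24a1, which encodes the enzyme that inactivates vitamin D. Some cell division genes were lower and, as in females, some cholesterol synthesis genes higher. Neither list passed with an estimated correlation (adjusted p = 0.306 and 0.276). Many ribosomal and respiratory chain genes were slightly higher in active males, by much less than 2-fold, and these lists did not pass with an estimated correlation either (0.616 and 0.605).

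Arntl was at 673 ± 139 and 102 ± 39.8 normalized counts, log2 fold 2.80 ± 0.34, adjusted p = 1.47e-05. Cry1 rose 6.55-fold (log2 fold 2.71 ± 0.26, adjusted p = 9.63e-07), and Npas2 3.30-fold (log2 fold 1.72 ± 0.21, adjusted p = 3.73e-06). Nfil3 (log2 fold 1.75 ± 0.21, adjusted p = 7.45e-06) and Clock (log2 fold 0.33 ± 0.06, adjusted p = 2.60e-04) were higher too, as were all 6 genes of the Bmal1 arm (camera adjusted p = 1.53e-14, and adjusted p = 7.04e-06 with an estimated correlation). Nr1d1 was 12.4-fold lower, at 133 ± 38.4 and 1623 ± 295 normalized counts, log2 fold -3.63 ± 0.17, adjusted p = 9.30e-13, and Dbp lower too, at 149.7 ± 75.3 and 1668 ± 164 (log2 fold -3.59 ± 0.22, adjusted p = 5.13e-10). Ciart (log2 fold -2.37 ± 0.25, adjusted p = 7.52e-07), Nr1d2 (log2 fold -1.54 ± 0.11, adjusted p = 2.06e-09), Bhlhe41 (log2 fold -0.96 ± 0.17, adjusted p = 3.46e-04), Per3 (log2 fold -0.88 ± 0.13, adjusted p = 1.11e-04) and Tef (log2 fold -0.45 ± 0.09, adjusted p = 0.00228) were lower. Per2 (log2 fold 0.98 ± 0.22, adjusted p = 0.00479) and Cry2, a cryptochrome repressor (log2 fold 0.32 ± 0.09, adjusted p = 0.0141), were higher. That made 7 lower, 2 higher and 4 not passing in the Per arm (camera adjusted p = 5.63e-07, and adjusted p = 0.154 with an estimated correlation).

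By the same measure the largest fall outside the clock in males was in Cyp24a1 (ENSMUSG00000038567), the enzyme that inactivates vitamin D. It was 5.67-fold lower in the active period, at 1522 ± 368 and 8802 ± 2939.9 normalized counts, log2 fold -2.50 ± 0.27, adjusted p = 4.42e-06. The highest active library, at 1848, lay below the lowest inactive one, at 5308. Lingo4, which encodes a leucine-rich repeat membrane protein, rose 4.13-fold (log2 fold 2.05 ± 0.22, adjusted p = 2.25e-07), and the kinase gene Nek5 fell (log2 fold -1.66 ± 0.30, adjusted p = 3.96e-04). Hsd11b2, the enzyme that shields the mineralocorticoid receptor from glucocorticoids, rose (log2 fold 0.37 ± 0.05, adjusted p = 2.25e-05), and the receptor itself, Nr3c2, fell (log2 fold -0.32 ± 0.06, adjusted p = 6.80e-04). The drug efflux pump Abcb1a fell (log2 fold -0.75 ± 0.15, adjusted p = 0.00112).

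Of 22 unfolded protein response genes 11 were higher and 11 did not pass in males (12 higher over the list alone, camera adjusted p = 2.47e-05, and adjusted p = 0.605 with an estimated correlation). Hyou1 (log2 fold 0.77 ± 0.12, adjusted p = 1.28e-04), the secreted chaperone-like Creld2 (log2 fold 1.05 ± 0.19, adjusted p = 0.00104) and the chaperone Hspa5 (log2 fold 0.76 ± 0.16, adjusted p = 0.00397) rose. Of 16 heat shock genes 7 were higher and 9 did not pass (11 higher over the list alone, camera adjusted p = 4.16e-06, and adjusted p = 0.536 with an estimated correlation), among them Stip1 (log2 fold 0.61 ± 0.12, adjusted p = 0.00125) and Ahsa1 (log2 fold 0.57 ± 0.11, adjusted p = 0.00178). Tsc22d3 rose 2.27-fold (log2 fold 1.18 ± 0.22, adjusted p = 0.00104) and Fkbp5 rose (log2 fold 0.68 ± 0.17, adjusted p = 0.0109), while the glucocorticoid list had 4 higher and 3 lower (camera adjusted p = 0.883). Cirbp fell (log2 fold -0.50 ± 0.12, adjusted p = 0.00644), and Rbm3 did not pass (adjusted p = 0.496).

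Of the transporters named for females, several changed in the same direction in males. Scnn1a (log2 fold 0.41 ± 0.06, adjusted p = 5.04e-05) and Avpr1a (log2 fold 0.83 ± 0.11, adjusted p = 6.75e-06) rose, and Slc9a3 (log2 fold -0.54 ± 0.07, adjusted p = 3.37e-06), Slc6a19 (log2 fold -0.88 ± 0.11, adjusted p = 1.36e-05), Slc2a2 (log2 fold -0.48 ± 0.06, adjusted p = 4.49e-06) and Kcnma1 (log2 fold -0.82 ± 0.22, adjusted p = 0.0101) fell. Aqp3 did not pass in males (adjusted p = 0.0589), and of 26 sodium, potassium and chloride transport genes 6 were higher and 4 lower (camera adjusted p = 0.961). The change of Slc22a4 differed between the sexes (difference 0.53 ± 0.13, adjusted p = 0.0276), a call lost in 4 of the analyses with a library left out. G6pc rose (log2 fold 0.75 ± 0.17, adjusted p = 0.00688) and Cpt1a (log2 fold -0.34 ± 0.06, adjusted p = 4.81e-04), Ppara (log2 fold -0.57 ± 0.11, adjusted p = 8.43e-04) and Wipi1 (log2 fold -0.69 ± 0.09, adjusted p = 1.17e-05) fell. Of 25 cholesterol synthesis genes 11 were higher and 14 did not pass (13 higher over the list alone, camera adjusted p = 4.16e-06, and adjusted p = 0.276 with an estimated correlation). Among them were Msmo1 (log2 fold 0.85 ± 0.12, adjusted p = 6.50e-05), Lss (log2 fold 0.47 ± 0.09, adjusted p = 5.22e-04), Mvd (log2 fold 0.46 ± 0.08, adjusted p = 1.69e-04) and Acat2 (log2 fold 0.39 ± 0.06, adjusted p = 5.62e-05), all enzymes of the pathway. Of 9 endothelial markers 5 were higher and 4 did not pass (6 higher over the list alone, camera adjusted p = 0.000236, and adjusted p = 0.526 with an estimated correlation), including the vessel receptors Flt1 (log2 fold 0.54 ± 0.09, adjusted p = 2.89e-04) and Tie1 (log2 fold 0.47 ± 0.09, adjusted p = 0.00104) and the glomerular endothelial Ehd3 (log2 fold 0.53 ± 0.09, adjusted p = 4.26e-04). Flt1 was also higher in active females, at 3574 ± 301 and 2594 ± 280 normalized counts, with no overlap of libraries. Female libraries overlapped between the periods for Tie1 and Ehd3.

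Some cell division genes were lower in active males. Of 24 cell cycle genes 7 were lower, 1 higher and 16 did not pass (16 lower and 1 higher over the list alone, camera adjusted p = 2.47e-05, and adjusted p = 0.306 with an estimated correlation). The proliferation marker Mki67 was at 124 ± 25.2 and 243 ± 43.3 normalized counts, log2 fold -0.98 ± 0.17, adjusted p = 2.17e-04. The mitotic regulators Cdc20 (log2 fold -1.13 ± 0.23, adjusted p = 0.00146) and Ccnb1 (log2 fold -1.28 ± 0.32, adjusted p = 0.00760) fell. The count of lower genes drops to 4 without male active replicate 2 or 5.

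Of 82 ribosomal protein genes 41 were higher in active males and 41 did not pass (63 higher over the list alone, camera adjusted p = 5.86e-15, and adjusted p = 0.616 with an estimated correlation). Rpl10a, a protein of the large subunit, rose 1.20-fold (log2 fold 0.26 ± 0.06, adjusted p = 0.00479). Its SD was 838 in active males, 245 in inactive males, and 73.4 and 235 in active and inactive females. Ndufa8 and Ndufs7, named next, were also most spread in active males. The fit shares 1 spread over all groups, so the SE and p-values of such genes may understate the spread of active males. Of 58 nuclear respiratory chain genes 25 were higher (44 over the list alone, camera adjusted p = 2.07e-12, and adjusted p = 0.605 with an estimated correlation), such as the complex I genes Ndufa8 (log2 fold 0.29 ± 0.06, adjusted p = 0.00263) and Ndufs7 (log2 fold 0.32 ± 0.08, adjusted p = 0.00577). Of 13 mitochondrially encoded genes 6 were lower (9 over the list alone, camera adjusted p = 0.000381, and adjusted p = 0.526 with an estimated correlation), and 3 without male inactive replicate 4. The ribosomal count is 65 without male active replicate 1, 12 without replicate 2, 18 without 5 and 27 without 6, and 18 and 13 without male inactive replicates 5 and 6. In the same order the respiratory count is 46, 11, 11, 16, 13 and 12. Other genes matched to these lists for level, length and GC content had median log2 folds of 0.14 in both cases, close to the 0.18 and 0.17 of the lists themselves.

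**Figure D2:**
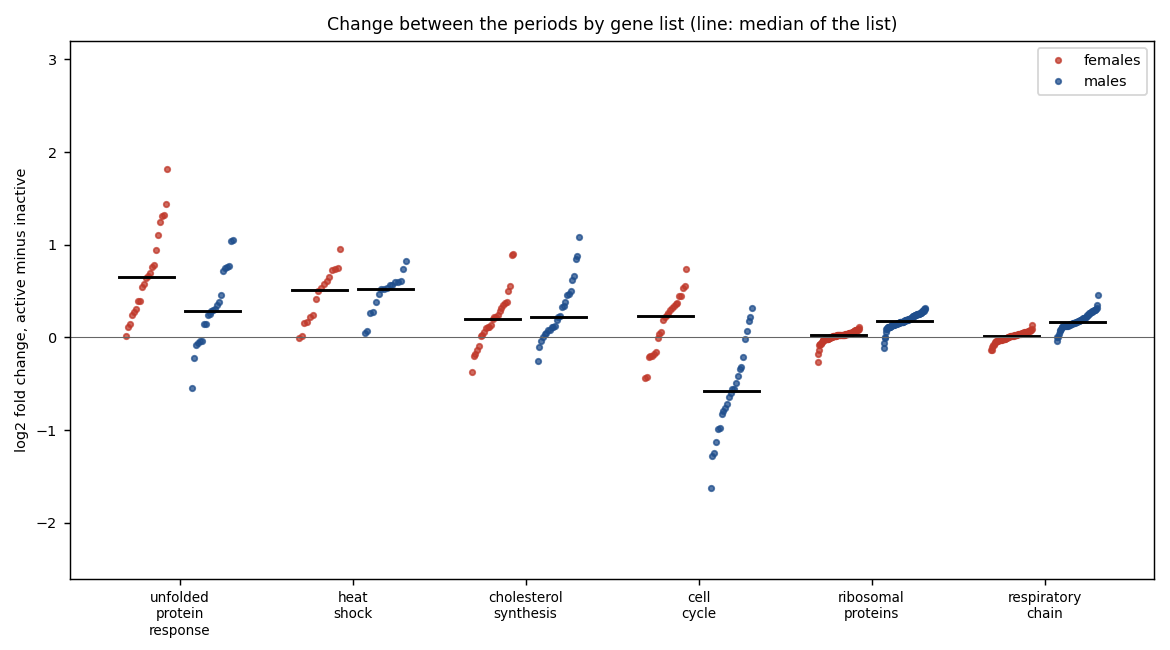
Log2 fold of active against inactive period for the members of 6 gene lists, in females and in males. Each point is a gene and each line the list's median. The medians of unfolded protein response and heat shock genes lay above 0 in both sexes. Ribosomal protein and nuclear respiratory chain genes lay slightly above 0 in males under every scaling, and in females around 0, where equal totals turned the medians of 0.02 and 0.01 into -0.01 and -0.02.

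In males 1461 genes were higher and 1204 lower in the active period, and 211 changed at least 2-fold. The median fold of the called genes was 1.25. With males alone in the model the calls were 998 higher and 758 lower, and with females alone 1553 and 1382. The near-equal totals of the sexes therefore rest on the spread shared by all groups. By the upper quartile there were 1181 higher and 1521 lower, and by equal totals 1130.0 and 1458. All 6 active libraries lay on the same side of all 6 inactive ones in each called gene named here other than Tef, Cry2, Nr3c2, Abcb1a, Stip1, Ahsa1, Kcnma1, G6pc, Flt1, Tie1, Ehd3, Rpl10a, Ndufa8 and Ndufs7.

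Part of the period response was shared by the sexes. Of the 4413 genes called in either sex 465 were higher in the active period in both sexes, where 116 would be shared by chance (Fisher p = 7.46e-177), and 344 were lower in both, where 84.1 would be (Fisher p = 3.20e-129). Another 35 were called in opposite directions. Over all tested genes the changes in females and males correlated with r = 0.38, from libraries with none in common.

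The period response also differed between the sexes. Several clock genes swung less in males, single cell division and unfolded protein response genes had a more negative change in males, and some male-biased genes of the proximal tubule were lower in active females and not in active males. The difference between the male and the female change passed for 470 genes, 245 more positive and 225 more negative in males, 48 of them at least 2-fold. These counts are less stable than the others, at 133 and 114 without a filter, 147 and 142 with a plain variance prior and 520.0 and 417 with DESeq2. With a library left out they ranged from 139 (without female active replicate 4) to 465 (without male active replicate 1) more positive and from 133 (without female inactive replicate 3) to 315 more negative, and the closing notes name the other libraries. Of the 470 genes 63 were called in both sexes, 35 of them in opposite directions, 224 in females alone, 163 in males alone and 20 in neither. Taken by sign alone, 357 moved in opposite directions.

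**Figure D3:**
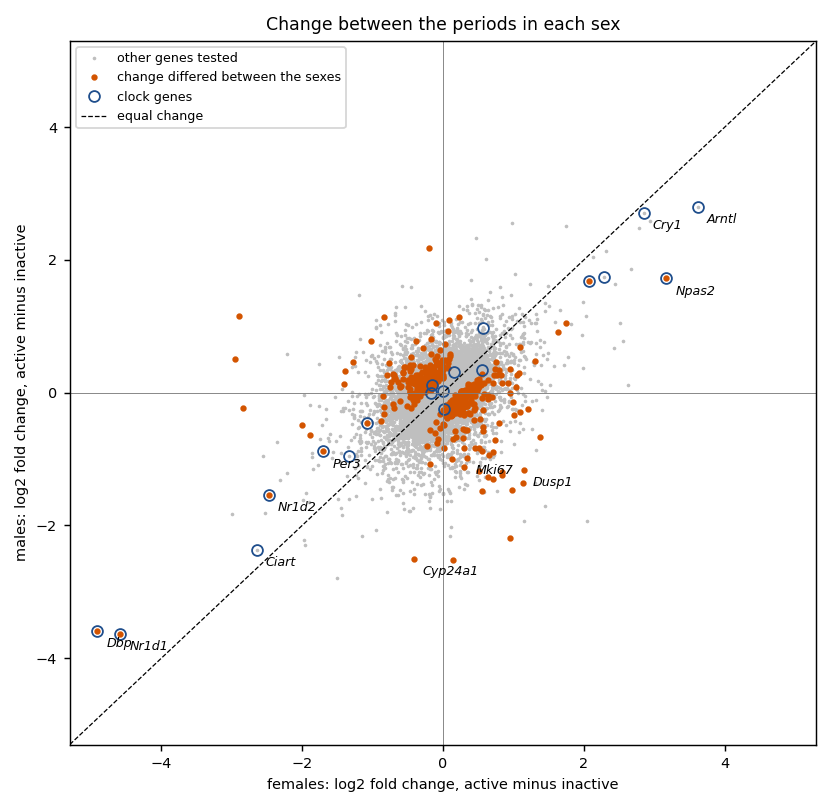
Change between active and inactive period in females and in males for 17333 genes, as log2 fold. Each point is a gene. Orange points are the 470 genes whose change differed between the sexes, circles mark clock genes, and the dashed line is equal change. Of the 16 clock genes called in either sex, 14 lay closer to 0 in males and Per2 and Cry2 farther from it.

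Npas2 rose less in males (difference -1.45 ± 0.30, adjusted p = 0.00998). Dbp (1.32 ± 0.31, adjusted p = 0.0242), Nr1d2 (0.93 ± 0.15, adjusted p = 0.00384), Per3 (0.82 ± 0.19, adjusted p = 0.0208) and Tef (0.63 ± 0.13, adjusted p = 0.0128) fell less in males. Arntl (-0.82 ± 0.48, adjusted p = 0.368) and Cry1 (-0.14 ± 0.37, adjusted p = 0.882) did not differ by this test. In the Bmal1 arm 2 of 6 genes were more negative in males (3 over the list alone, camera adjusted p = 0.000446, and adjusted p = 0.0206 with an estimated correlation). In the Per arm 5 of 13 were more positive, also over the list alone (camera adjusted p = 8.71e-06, and adjusted p = 0.208 with an estimated correlation). The fifth, Nr1d1 (0.95 ± 0.25, adjusted p = 0.0379), loses its call without female active replicate 4 or 6, female inactive replicate 2, 3, 5 or 6, male active replicate 4 or 5 or male inactive replicate 3 or 4.

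Cyp24a1 fell in active males and not detectably in females, at 2584 ± 687 and 3601 ± 1423 (difference -2.09 ± 0.38, adjusted p = 0.00713). The immediate early phosphatase gene Dusp1 was at 3161 ± 1368 and 1346 ± 317 in active and inactive females and at 1317 ± 462 and 3134 ± 1658 in males (difference -2.31 ± 0.48, adjusted p = 0.0146). Its libraries overlapped between the periods, at 1401 to 5197 and 933 to 1742 in females and 808 to 2004 and 1481 to 6057 in males. The glucocorticoid-induced GTPase gene Rasd1 (-2.07 ± 0.42, adjusted p = 0.0119) and the chemokine gene Cxcl1 (-2.44 ± 0.56, adjusted p = 0.0198) had the same pattern of means, while Selenoh, which encodes a selenoprotein, had the reverse (1.07 ± 0.21, adjusted p = 0.00713). Active and inactive male libraries overlapped for Rasd1, Cxcl1 and Selenoh as well, and female libraries for Rasd1. Hsd11b2 was more positive in males (0.30 ± 0.08, adjusted p = 0.0249).

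Of 24 cell cycle genes 5 were more negative in males (13 more negative and 1 more positive over the list alone, camera adjusted p = 9.97e-07, and adjusted p = 0.208 with an estimated correlation). They include Mki67 (-1.32 ± 0.24, adjusted p = 0.00465), Cdc20 (-1.42 ± 0.33, adjusted p = 0.0179) and the mitotic motor Kif11 (-1.28 ± 0.30, adjusted p = 0.0198). Without female active replicate 3 or 4, female inactive replicate 2 or 3, male active replicate 2, 5 or 6, or male inactive replicate 3, 5 or 6, that count is 3. Of 22 unfolded protein response genes 4 were more negative in males (12 over the list alone, camera adjusted p = 9.46e-09, and adjusted p = 0.436 with an estimated correlation), led by Xbp1, the transcription factor of that response (-0.67 ± 0.13, adjusted p = 0.00780). That count is 2 without female inactive replicate 3, 9 without female inactive replicate 6 or male active replicate 2, and 7 without male active replicate 6.

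Of 22 genes known as androgen-dependent or male-biased, 4 had a period change that was more positive in males than in females (7 more positive and 2 more negative over the list alone, camera adjusted p = 0.0123, and adjusted p = 0.526 with an estimated correlation). The transporter Slc22a28 fell in active females, at 936 ± 147 and 1576 ± 348 normalized counts, log2 fold -0.73 ± 0.12, adjusted p = 9.27e-05, and was at 11948 ± 1007 and 10732 ± 742 in males (difference 0.89 ± 0.16, adjusted p = 0.00621). The hydroxysteroid dehydrogenase genes Akr1c21 (0.70 ± 0.15, adjusted p = 0.0145) and Hsd17b11 (0.43 ± 0.10, adjusted p = 0.0186) and the glutathione transferase gene Gsta2 (0.59 ± 0.12, adjusted p = 0.00941) differed the same way. Gsta2 was higher in females in these data, at 15460.0 ± 1663 against 5735 ± 502 in the active period, unlike the other genes named from this list. Fxyd4, a sodium pump regulator of the collecting duct (0.57 ± 0.11, adjusted p = 0.00497), Stard4, a cholesterol carrier (0.41 ± 0.09, adjusted p = 0.0150), and the collagen gene Col1a1 (0.78 ± 0.19, adjusted p = 0.0222) were more positive in males as well. Slc22a28 belongs to a family of near-identical genes, so reads of its relatives may be counted with it.

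In the active period males and females had widely different kidney RNA. Male kidneys had far more RNA of some genes of steroid and drug metabolism and of organic anion transport. Female kidneys had far more RNA of some other transporters and of the prolactin receptor. Most markers of podocytes, vessels, connective tissue and the distal convoluted tubule were higher in females, as were most interferon-response genes, though these lists did not pass with an estimated correlation (adjusted p = 0.103, 0.616, 0.655, 0.526 and 0.616).

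The transporter Slco1a1 (ENSMUSG00000041698), which moves organic anions, was near 0 in active females, with 10 reads over the 6 libraries, and at 28818 ± 2687 in males (log2 fold 13.80 ± 0.44, adjusted p = 1.98e-16), a ratio of means of 18411. The amino acid transporter Slc7a13 (ENSMUSG00000041052) was at 58.7 ± 26.8 in females and 48631 ± 3450.3 in males, an 828-fold difference. Pzp, a protease-binding protein (1055-fold), Cyp2j13, a cytochrome P450 (661-fold), and Ugt2b37, a glucuronosyltransferase (log2 fold 7.72 ± 0.22, adjusted p = 1.87e-17), were higher in males. Mpped1, which encodes a metallophosphoesterase, had 2 reads over the 6 female libraries and was 957-fold higher in males (counting interval 282 to 8416). In the other direction Ugt1a2 (ENSMUSG00000090171), a glucuronosyltransferase, was at 12464 ± 2449.9 in females and 8.62 ± 3.90 in males (1446-fold), though it shares exons with the rest of its gene cluster. The amino acid transporter Slc7a12 (151-fold) and the phosphate and anion transporter Slc17a2 (125-fold) were higher in females. Atp13a4, a cation-transporting ATPase, had no reads in active males and was at least 246-fold higher in females (floor of 3 reads over the 6 libraries). Tmprss6, a membrane protease, had 2 reads in males and was 293-fold higher in females (counting interval 83.2 to 2481). These floors and intervals cover counting error only, and the log2 folds, taken after adding 1, understate such ratios.

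Single genes of steroid and drug metabolism differed strongly. Cyp7b1, which hydroxylates oxysterols and steroids, was at 10442 ± 1195 in active males and 119.7 ± 23.9 in females (log2 fold 6.46 ± 0.11, adjusted p = 1.42e-25). Acsm3, a medium-chain acyl-CoA synthetase (log2 fold 7.51 ± 0.17, adjusted p = 2.37e-19), Cyp4b1, a cytochrome P450 (log2 fold 4.24 ± 0.10, adjusted p = 1.14e-20), Hsd17b2, which inactivates sex steroids (log2 fold 3.02 ± 0.17, adjusted p = 2.16e-14), Srd5a1, which makes dihydrotestosterone (log2 fold 1.53 ± 0.11, adjusted p = 2.15e-12), and the estrogen receptor Esr1 (log2 fold 1.35 ± 0.11, adjusted p = 2.33e-11) were higher in males. Of 14 genes of sex steroid receptors and synthesis 6 were higher and 3 lower (camera adjusted p = 0.239). Of 22 genes known as androgen-dependent or male-biased 19 were higher, 2 lower and 1 did not pass (camera adjusted p = 4.86e-15, and adjusted p = 0.00397 with an estimated correlation). Of 9 genes known as female-biased 7 were lower in males and 2 higher (camera adjusted p = 0.000343, and adjusted p = 0.103 with an estimated correlation). Prlr, the prolactin receptor, was at 11342 ± 2862 in females and 285 ± 175 in males (log2 fold -5.49 ± 0.37, adjusted p = 4.58e-11), and Abcc3, an organic anion export pump, 26.3-fold higher in females (log2 fold -4.65 ± 0.19, adjusted p = 5.33e-16). All 4 Y-linked genes were higher in males (camera adjusted p = 2.21e-07, and 0.00381 with an estimated correlation), and 5 of 6 X-linked genes expressed from both copies were lower (camera adjusted p = 0.000286, and 0.0303 with an estimated correlation), such as the demethylase gene Kdm6a (log2 fold -1.19 ± 0.08, adjusted p = 1.27e-13).

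The overall count depends on the scaling between the sexes. By the authors' scaling 5219 genes were higher and 5290 lower in active males (2635 and 8822 with equal totals), 1749 of them at least 2-fold, with a median fold of 1.44 among called genes. The median log2 fold of all genes moves from -0.05 to -0.12 with the upper quartile and to -0.32 with equal totals, so directions below are relative to that median and hold under each scaling unless stated. Of all tested genes 60.6% were called by sex in the active and 55.7% in the inactive period, so the counts within lists below stand against these shares. The authors' normalized totals were 37.9 M in active males and 31.3 M in active females.

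In the inactive period the same sex differences stood out. Male kidneys again had more RNA of some genes of steroid metabolism and organic anion transport, and female kidneys of other transporters. Connective tissue and vessel markers and interferon-response genes were again mostly higher in females, though these lists did not pass with an estimated correlation (adjusted p = 0.434, 0.455 and 0.526).

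Slco1a1 was at 29885 ± 4881 and 8.49 ± 6.29 normalized counts, log2 fold 11.87 ± 0.44, adjusted p = 3.32e-15, a ratio of means of 3519. Slc7a13 (720-fold), Pzp (557-fold), Cyp2j13 (482-fold) and Apoh, a phospholipid-binding plasma protein (273-fold), were higher in males. Mpped1 had no reads in inactive females and was at least 621-fold higher in males. Ugt1a2 (1985-fold), Slc17a2 (101-fold) and Slc7a12 (69.7-fold) were higher in females, and Atp13a4, with 2 reads in inactive males, was 334-fold higher (counting interval 84.0 to 2505). Cyp7b1 (log2 fold 6.47 ± 0.11, adjusted p = 1.69e-25), Acsm3 (log2 fold 7.62 ± 0.17, adjusted p = 1.89e-19), Cyp4b1 (log2 fold 4.71 ± 0.10, adjusted p = 1.36e-21), Hsd17b2 (log2 fold 3.23 ± 0.17, adjusted p = 6.48e-15) and Esr1 (2.43-fold, adjusted p = 8.89e-11) were higher in males, and Prlr (log2 fold -5.27 ± 0.37, adjusted p = 1.24e-10) and Abcc3 (log2 fold -5.14 ± 0.19, adjusted p = 9.00e-17) in females. The androgen list again had 19 of 22 genes higher and 2 lower (camera adjusted p = 5.69e-16, and adjusted p = 0.00381 with an estimated correlation), and the female-biased list 7 lower and 2 higher of 9 (camera adjusted p = 8.24e-05, and adjusted p = 0.0670 with an estimated correlation). All 4 Y-linked genes were higher (camera adjusted p = 2.49e-08, and 0.00295 with an estimated correlation) and 5 of 6 X-linked genes expressed from both copies lower (camera adjusted p = 0.000446, and 0.0375 with an estimated correlation).

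In total 4844 genes were higher and 4818 lower in inactive males (2051 and 9054 with equal totals), 1506 of them at least 2-fold, with a median fold of 1.41 among called genes. Across periods 4084 genes were higher in males both times, where 1459 would be shared by chance if calls were independent. Another 3692 were lower both times, where 1470.4 would be, and 45 were called in opposite directions. The sex differences of the periods correlated with r = 0.88. Cyp2j13, Ugt2b37, Slco1a1 and Ugt1a2 have close relatives, and the strand setting of the counting is not given, so reads of a neighbour or relative may be included.

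Transport genes differed by sex in both periods. The organic anion transporter Slc22a6 was higher in males in the active (log2 fold 2.21 ± 0.17, adjusted p = 2.65e-10) and the inactive period (log2 fold 1.70 ± 0.17, adjusted p = 2.24e-08), as was Slco3a1 (log2 fold 2.25 ± 0.08, adjusted p = 4.06e-19, and 2.45, adjusted p = 6.37e-20). The organic anion transporter Slc22a29 was lower in males (-3.91 and -4.35). Pairs of values after a gene are, here and below, its log2 folds of males against females in the active and the inactive period. Of 28 organic ion transporters 18 were higher and 7 lower in active males and 17 higher and 7 lower in inactive males (camera adjusted p = 0.00268 and 0.0101, and adjusted p = 0.536 and 0.616 with an estimated correlation). The thiazide-sensitive cotransporter Slc12a3 was at 61715 ± 4647 in active females and 36691 ± 1826 in active males (log2 fold -0.75 ± 0.06, adjusted p = 1.36e-12). The loop diuretic target Slc12a1 (log2 fold -0.76 ± 0.06, adjusted p = 4.21e-12), the distal potassium channel Kcnj10 (log2 fold -0.64 ± 0.05, adjusted p = 4.95e-12), the WNK regulator Klhl3 (log2 fold -0.66 ± 0.07, adjusted p = 9.23e-10) and Kcnj1 (log2 fold -0.56 ± 0.05, adjusted p = 2.72e-10) were lower in active males, and the phosphate transporter Slc34a1 higher (log2 fold 0.83 ± 0.06, adjusted p = 1.02e-12). Of 26 sodium, potassium and chloride transport genes 4 were higher and 14 lower in active males, and 7 higher and 16 lower in inactive males (camera adjusted p = 0.116 and 0.0554). Sgk1 was lower in active males (log2 fold -2.02 ± 0.29, adjusted p = 4.60e-06), and Fkbp5 higher (log2 fold 1.64 ± 0.17, adjusted p = 3.99e-08).

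Of 58 nuclear respiratory chain genes 57 were higher in active and 52 in inactive males (camera adjusted p = 5.69e-16 and 6.89e-11, and adjusted p = 0.526 and 0.616 with an estimated correlation), falling to 41 and 14 with equal totals. The complex I gene Ndufv1 was among them (0.72 and 0.59). Of 82 ribosomal protein genes 70 were higher in active males (camera adjusted p = 4.72e-09, and adjusted p = 0.655 with an estimated correlation), 12 with equal totals. In inactive males 25 were higher (camera adjusted p = 0.00517, and adjusted p = 0.822 with an estimated correlation), and equal totals turned the median from 0.12 to -0.16. The mitochondrial dehydrogenase Acadl (0.74 and 0.84), the cholesterol enzyme Hmgcs1 (1.12 and 1.11) and the pyruvate carboxylase Pcx (1.04 and 0.89) were higher in both periods. Of 17 autophagy genes 12 and 9 were higher in active and inactive males (camera adjusted p = 0.00138 and 0.000937, and adjusted p = 0.304 and 0.277 with an estimated correlation), with medians that equal totals turned from 0.19 and 0.20 to -0.09 and -0.08. The autophagy receptor Sqstm1 (0.99 and 0.75) and the autophagosome protein Map1lc3a (1.26 and 1.12) were among them.

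Many markers of cell types other than the proximal tubule were lower in male RNA. The proximal tubule markers went both ways, with Slc7a13, Slc22a6 and Slc34a1 among those higher in males. Their median log2 folds were -0.15 in the active and -0.25 in the inactive period. The medians of all genes were -0.05 and -0.04. Of 8 podocyte markers 8 were lower in active and 7 in inactive males (camera adjusted p = 1.90e-05 and 0.000396, and adjusted p = 0.103 and 0.208 with an estimated correlation). The podocyte surface protein Podxl (-0.78 and -0.72) was lower in both periods, and Wt1, the podocyte transcription factor (log2 fold -1.06 ± 0.09, adjusted p = 3.80e-11), in active males. Of 9 endothelial markers 8 and 9 were lower (camera adjusted p = 0.00680 and 2.70e-05, and adjusted p = 0.616 and 0.455 with an estimated correlation), such as the junction protein Cdh5 (-0.77 and -0.92) and Flt1 (-0.86 and -0.94). Of 9 fibroblast and pericyte markers 7 and 9 were lower (camera adjusted p = 0.0338 and 4.47e-05, and adjusted p = 0.655 and 0.434 with an estimated correlation), such as the matrix protein Lum (-1.12 and -1.57). Of 6 distal convoluted tubule markers 5 were lower in each period (camera adjusted p = 0.0200 and 0.00680, and adjusted p = 0.526 and 0.434 with an estimated correlation). Of 9 intercalated cell markers 7 and 6 were lower (camera adjusted p = 0.0106 and 0.0237, and adjusted p = 0.605 and 0.616 with an estimated correlation), such as the proton pump subunit Atp6v0d2 (-0.82 and -0.42).

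**Figure D4:**
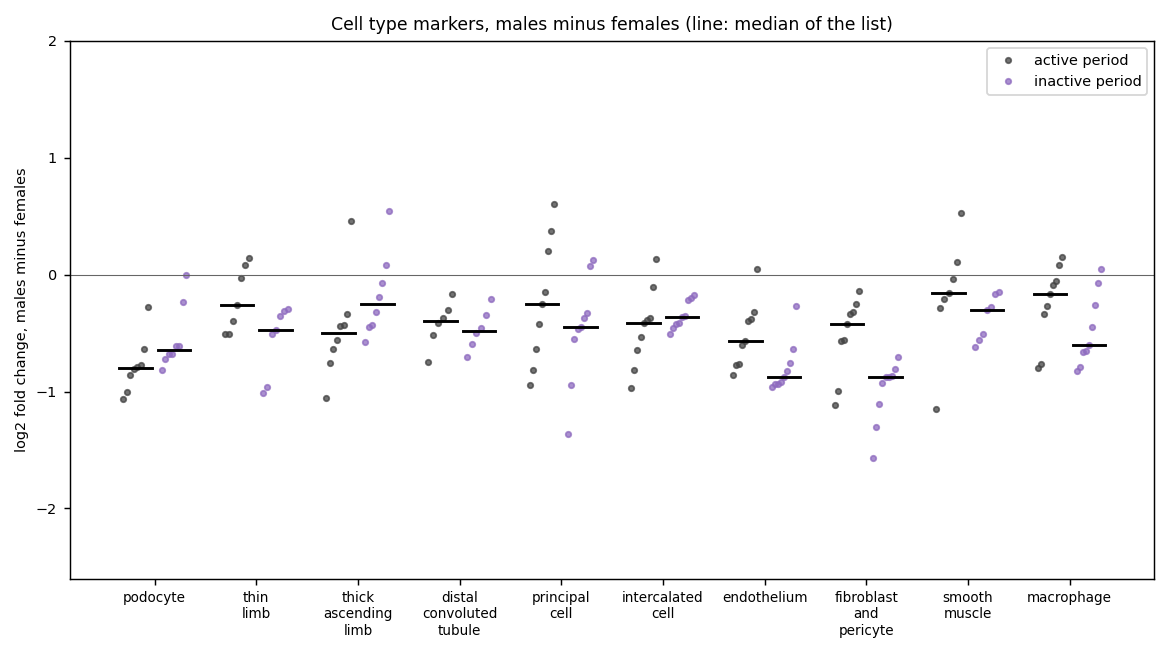
Log2 fold of males against females for markers of 10 kidney cell types, in the active and the inactive period. Each point is a marker gene and each line the median of its cell type. All 10 medians lay below 0 in both periods, from -0.80 (podocyte) to -0.16 (smooth muscle) in the active and from -0.88 (fibroblast and pericyte) to -0.25 (thick ascending limb) in the inactive period. Equal totals lower them all further.

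Of 19 interferon-response genes 12 were lower in active and 16 in inactive males (camera adjusted p = 0.00141 and 4.16e-05, and adjusted p = 0.616 and 0.526 with an estimated correlation). The guanylate-binding protein gene Gbp3 (-2.55 and -2.48), the antiviral Rsad2 (-0.95 and -0.95) and Ifit2 (-0.98 and -0.96) were among them. Rsad2 was also higher in the active period in females (log2 fold 0.64 ± 0.10, adjusted p = 4.96e-05) and males (log2 fold 0.64 ± 0.10, adjusted p = 1.03e-04). Of 16 heat shock genes 10 were higher in males in each period (camera adjusted p = 0.0140 and 0.00242, and adjusted p = 0.666 and 0.655 with an estimated correlation), such as the mitochondrial chaperonin Hspd1 (0.76 and 0.86). Clock genes differed by sex within a period as well. Tef (log2 fold 0.59 ± 0.09, adjusted p = 6.78e-06), Dbp (log2 fold 0.98 ± 0.22, adjusted p = 5.38e-04), Nr1d2 (log2 fold 0.70 ± 0.11, adjusted p = 7.17e-06) and the ubiquitin protease Usp2 (log2 fold 0.74 ± 0.12, adjusted p = 2.33e-05) were higher in active males, and Npas2 (log2 fold -0.88 ± 0.21, adjusted p = 7.77e-04) and Nfil3 (log2 fold -0.80 ± 0.21, adjusted p = 0.00216) lower. In the sex comparisons all 6 male libraries lay on the same side of all 6 female ones in each named gene, except for Lum, Dbp, Npas2 and Nfil3 in the active period.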

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

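The other splits of the libraries, the scaling and phase tests of the clock genes, the tests of how much of the ribosomal and respiratory change goes with gene properties, and the scaling and proximal tubule tests of the cell type markers were chosen only after the result was seen.

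Splitting the libraries in other ways gave fewer genes than the real comparison in most cases. Of 100 splits, the real one included, 1 gave as many genes as the 2592 for the period in females (highest other 473), 1 as many as the 2665 in males (963), 1 as many as the 10509 for sex in the active period (7559) and 1 as many as the 9662 in the inactive period (5934). In each of these the highest other split kept 5 of 6 libraries of a group together. For the 470 interaction genes 2 of 100 splits gave as many, the highest other 602. At a share under 0.05 this argues against chance as the whole source of each count. It does so less for the interaction, where another split gave more genes than the real one. Splits cannot test a cause that follows the groups.

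Most clock genes had a smaller estimated change between periods in males than in females. The difference passed for some, among them Npas2, Dbp, Nr1d2, Per3 and Tef, and not for Arntl or Cry1. The slope of the male on the female changes over 19 clock genes was 0.75, between 0.733 and 0.774 when any library was left out, which argues against a single library as the whole cause. All 14 clock genes called in females changed less in males under 4 scalings, but these genes were chosen by their female change, so that count decides nothing. Among the 16 called in either sex, 2 changed more in males, Per2 and Cry2. With 2 collection times a smaller swing and a shifted phase cannot be told apart, so a candidate explanation of either kind stays open, and a sex difference in the clock itself was not tested.

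Ribosomal protein and respiratory chain genes were slightly higher in active males, with median log2 folds of 0.179 and 0.170. Lists matched for level, length and GC content had medians of 0.140 and 0.138 themselves, so a trend with these properties may account for most of the size. Of 10000 matched lists 0.740% and 4.16% moved as far. In females, where the ribosomal median was only 0.024, 1.45% did. The draws take each gene alone, while members of a list may move together, so these shares cannot decide whether the trend is the whole cause. No library alone carries the rise in males, as the lowest medians with a library left out were 0.113 and 0.114, both without male active replicate 2. Changes followed GC content with r = 0.181 in males and r = 0.217 in the interaction, and whether that trend is technical stays open. Small differences in RNA quality between male libraries were not tested.

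Markers of 10 cell types were lower in male than in female RNA. The median of the 81 markers minus that of all genes was -0.350 in the active period and 10 of 10 types lay below 0, which argues against the scaling, since a factor moves markers and other genes alike. The medians of the types ran from -0.798 in podocytes to -0.160 in smooth muscle (permutation p = 0.0194 over 100000 permutations of the marker genes). Markers of a type come from the same libraries and may move together, so this p does not measure the spread between samples. It cannot decide whether a larger share of proximal tubule RNA in males is the whole cause. The proximal tubule markers themselves had a median of -0.153, against -0.045 for all genes. They went both ways, with Slc7a13, Slc22a6 and Slc34a1 among those higher in males, so their median cannot decide the share either. The most abundant distal marker, Slc12a3, was at 61715 ± 4647 in active females and 36691 ± 1826 in active males. Fewer or smaller cells of these types, or less of their RNA per cell, stay open and untested.

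Of 604 groups of 6 values tested for a library far from the rest, 41 passed at the 1 in 20 level, where 30.2 would by chance. Female active replicates 2 and 3 had 5 of them each and female inactive replicate 6 had 4. The values in brackets are the gap to the next library as a share of the range of the 6. The depth of female active replicate 4 was high (0.657). Values at 1 come from genes with reads in a single library of the group.

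Among clock and stress genes the values were Arntl low in male active replicate 5 (0.725), Ciart low in male active replicate 1 (0.645), Usp2 high in female active replicate 2 (0.653), Creld2 low in female active replicate 2 (0.656), Hsp90ab1 high in female inactive replicate 6 (0.650), Tsc22d3 high in female active replicate 2 (0.692) and Hspd1 low in female active replicate 3 (0.741). Among transport genes they were Aqp3 low in male active replicate 2 (0.736), Slc22a4 high in female active replicate 2 (0.714), Slc7a13 low in female active replicate 2 (0.649), Slc7a12 high in male inactive replicate 5 (0.830), Slc12a3 low in female inactive replicate 1 (0.702), Atp6v0d2 low in female inactive replicate 1 (0.627) and Atp13a4 high in female inactive replicate 1 (0.641) and male inactive replicate 2 (1).

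Among metabolic genes they were G6pc low in male active replicate 1 (0.70) and male inactive replicate 2 (0.721), Mvd high in female inactive replicate 6 (0.677), Hmgcs1 high in female inactive replicate 6 (0.628), Hsd17b11 low in male inactive replicate 1 (0.678), Cyp7b1 low in female active replicate 3 (0.715), Acadl low in female active replicate 3 (0.687) and male active replicate 1 (0.634), and Ugt1a2 low in female inactive replicate 5 (0.767). Among the others they were Creg2 low in male inactive replicate 4 (0.657), Nrap low in female inactive replicate 6 (0.681), Nek5 low in female active replicate 4 (0.647), Flt1 low in female inactive replicate 4 (0.635) and high in male inactive replicate 2 (0.634), Prlr high in male inactive replicate 5 (0.646), Spp1 high in male inactive replicate 1 (0.712), Fgb high in female inactive replicate 5 (0.643), and Lum low in female active replicate 6 (0.635) and high in male active replicate 4 (0.696). Mpped1 was high in female active replicate 1 (1), Tmprss6 in male active replicate 5 (1), Eif2s3y in female inactive replicate 2 (1) and Kdm5d in female active replicate 3 (1), and Kdm6a was low in female active replicate 3 (0.631) and male inactive replicate 1 (0.668).

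The named genes whose period change differed between the sexes, as male minus female log2 change, were Npas2 (-1.45), Nr1d1 (0.95), Dbp (1.32), Nr1d2 (0.93), Per3 (0.82) and Tef (0.63) of the clock. Of stress, signalling and cell division genes there were Hsp90b1 (-0.59), Xbp1 (-0.67), Dusp1 (-2.31), Rasd1 (-2.07), Cxcl1 (-2.44), Mki67 (-1.32), Cdc20 (-1.42), Kif11 (-1.28), Sqstm1 (0.24) and Selenoh (1.07). Of transport and metabolism there were Slc22a4 (0.53), Slc22a28 (0.89), Slc34a1 (0.35), Slc12a1 (-0.31), Atp6v0d2 (-0.39), Fxyd4 (0.57), Cyp24a1 (-2.09), Hsd11b2 (0.30), Gsta2 (0.59), Akr1c21 (0.70), Hsd17b11 (0.43) and Stard4 (0.41). The remaining genes were Nrap (1.25), Krt8 (0.31), Col1a1 (0.78) and Col3a1 (0.69). Of these 32 genes 23 kept their call without any library, and Nr1d1, Nrap, Hsp90b1, Slc22a4, Slc12a1, Sqstm1, Krt8, Col3a1 and Atp6v0d2 did not.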

How the results depend on the processing

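Rescaling to equal totals was chosen only after the group totals were seen to differ between the sexes, and the other alternatives were set before the data were examined.

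Equal totals reversed 5 named sex differences, all small. In the active period Hlf became -0.0067, mt-Nd4 -0.041 and Csf1r -0.128, and in the inactive period Aqp1 became -0.063 and Fbp1 -0.0034. The reversal follows from the construction, since equal totals lower the male values against the female ones. Over all settings that kept every library, equal totals included, 6444 of 6623 values of named genes stayed as they were. Of the rest 174 were weaker and these 5 reversed. With a library left out 6977 of 7452 did, 475 were weaker and 0 reversed.

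The counts by sex moved most with equal totals, to 2635 higher and 8822 lower in active males and 2051 higher and 9054 lower in inactive males, again by construction. For the period in males 758 genes were lower with only the 2 groups compared, against 1204. The folds are the same in that fit, so the difference comes from the estimate of the spread and its degrees of freedom. Females went the other way, from 1382 higher and 1210 lower to 1553 and 1382. The interaction had 133 higher and 114 lower without a filter, 147 and 142 with a plain variance prior, and 520 and 417 with DESeq2. The cause was not tested for the counts of the interaction. Of the list tests 10 passed with an estimated correlation against 73 with the preset one. Only this setting differed between the runs, so the drop follows from it. The 10 were the Bmal1 arm in both sexes and in the interaction, the Per arm in females, and the androgen, Y-linked and X-linked lists in both periods. With TMM 74 passed. By edgeR the counts higher and lower were 1358 and 1284 in females, 1528 and 1145 in males, 312 and 225 for the interaction, 5250 and 5182 in the active and 4749 and 4873 in the inactive period.

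With a library left out, period calls in females ranged from 1092 to 1468 higher and 969 to 1221 lower, and in males from 1015 to 1866 higher and 820 to 1408 lower. Sex calls ranged from 5006 to 5226 higher and 4987 to 5252 lower in the active period, and 4597 to 4770 and 4509 to 4666 in the inactive. Interaction calls ranged from 139 to 465 higher and 133 to 315 lower. The higher count was 139 without female active replicate 4, 154 and 157 without female inactive replicates 2 and 3, 465 and 154 without male active replicates 1 and 5, and 153 without male inactive replicate 3. The lower count was 137 without female active replicate 4, 139 and 133 without female inactive replicates 2 and 3, and 140 without male inactive replicate 3. With pseudocount 5, no filter, TMM or edgeR, the alternatives run for the overlaps, the shared period calls numbered 569 to 824, against 809, and the shared sex calls 7143 to 7825, against 7776.

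With the number in the titles as a block, the counts higher and lower were 309 and 222 for the interaction, 5016 and 5139 for sex in the active period and 4649 and 4676 in the inactive. The correlations of the 12 pairs of the same number were -0.104 to 0.124, with 1 over 0.1, and 5 of 12 male libraries correlated best with the female of their own number, which leaves open whether the numbers pair them.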

Other observations

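The test of the Bmal1 arm against the Per arm within groups was chosen only after the result was seen, and the test of the immediate early genes against the Per genes before.

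Single genes of further kidney systems differed by sex, though the lists below did not pass and 60.6% and 55.7% of all genes were called by sex in the active and inactive period. Of 12 genes of the renin-angiotensin and endothelin systems 2 were higher and 7 lower in males in each period (camera adjusted p = 0.154 and 0.20), and the converting enzyme gene Ace was higher (2.44-fold and 2.62-fold). Of 15 tubular injury genes 2 were higher and 6 lower in active males, and 2 and 7 in inactive males (camera adjusted p = 0.297 and 0.150), with the matrix protein Spp1 (-1.41 and -1.23), the adhesion molecule Vcam1 (-0.76 and -1.04) and the fibrinogen chain Fgb (-2.85 and -1.84) lower and the keratin Krt8 (0.85 and 0.53) higher. Of 17 water and urea transport genes 5 were higher and 9 lower in active males, and 2 and 7 in inactive males (camera adjusted p = 0.357 and 0.219). Hsd11b1, which activates glucocorticoids, was higher in males (1.57 and 1.78), and Cebpd, a glucocorticoid-induced transcription factor, lower (-1.92 and -1.45). Fgb was higher in the active period in females (log2 fold 1.05 ± 0.24, adjusted p = 0.00331). The 7 fat cell markers did not move as a list with the period in females or males (camera adjusted p = 0.933 and 0.821) or with sex in the active or inactive period (0.914 and 0.949).

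Libraries of the same period could have been collected at slightly different clock times, which would spread clock genes within a group. If so, the Bmal1 arm and the Per genes of a library should deviate in opposite directions. Among the 12 inactive libraries no such relation passed, with r = 0.0248 (permutation p = 0.941, rank correlation 0.0350, -0.474 without the 2 farthest libraries, -0.64 in females and 0.409 in males), and among the 12 active libraries r was -0.093 (p = 0.760, -0.575 in females and 0.412 in males). The females lean the way such a spread predicts and the males the other way, with 6 libraries each. The arm mean cannot decide this, since its genes did not always move together. Inactive female replicates 3, 5 and 6 were lowest in Arntl (36.2 to 76.9, others 149 to 164). They were highest in Cry1 of the same arm, in Ciart and in Per2 (1627 to 2335, others 987 to 1177). Among inactive males replicate 2 had the same pattern, lowest in Arntl (39.9) and highest in Cry1 (164), Ciart (448) and Per2 (2012). Replicate 4 did not, being low in Arntl (77.0), Cry1 (57.7) and Per2 (982). These genes were picked after the result was seen, so a spread in collection time stays open. Immediate early genes and Per genes had r = 0.390 in the inactive (p = 0.196) and r = 0.667 in the active libraries (p = 0.0394, adjusted over 4 relations 0.158, rank correlation 0.455), so handling before collection may have moved both in active libraries, but this does not pass the adjustment.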
